A study of Mus musculus with 10 samples.

How the data were processed

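Total RNA was extracted from frozen prostates of 10 mice, 5 per diet, reverse transcribed, labelled with biotin and hybridised to whole-transcript GeneChip arrays, per the labels' protocols. The values used are the processed table that the authors deposited, with 41345 probe sets and 1 column per mouse, and its log2 scale was inferred from the range of 0.31 to 13.64 in the deposited values. Partek software was used, per the submitters' processing notes. Its version, the background correction, the normalization and the summarisation of probes are not given in the sources used here. The array medians lay between 4.39 and 4.54, and the values were not centred per gene. A normalization that forces arrays to similar distributions can hide a shift shared by most genes. Raw scanner values were not used here, so no background level per probe was available, and the number of arrays sets the precision.

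Probe sets were named through the platform annotation. A single gene symbol was given for 23521 probe sets, several symbols for 1820 and none for 16004, and probe sets of the last kinds were left unnamed. Of the 22180 named genes, 21994 symbols were found in a mouse RefSeq gene table (assembly GRCm38.p6), which changed none of them. The annotation names no genome build, so no coordinates are given. For the 1082 genes with several probe sets, the one with the highest mean over all 10 arrays was used. Genes in the lowest 25% of mean expression (log2 of 3.78 or less) were left out as dim, which left 16635 genes. The filter takes no account of the groups.

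Groups and replicate numbers came from the sample labels. HFD was compared with CD by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates) with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are HFD minus CD on the log2 scale with the moderated standard error. A looser count took genes with at least 1.5-fold difference and an unadjusted p under 0.05. In all, 31 gene lists for cell types, tissues and pathways were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. Lists with fewer than 5 measured genes were not tested, which left 30. List means per mouse were compared by a 2-sided exact permutation test over every assignment of 5 against 5 mice, for which the smallest possible p is 0.00794. Mean values are given with the SD over 5 mice. The labels give no batch, litter or collection time, and no such effect could be fitted.

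The groups, tests, lists and the rule for naming genes were fixed before the data were examined. The rule took, in each direction, the 15 genes with the largest fold among those past the threshold. Where fewer passed, it was filled with genes of at least 1.5-fold difference and an unadjusted p under 0.01, which are named as not past the threshold. Predicted gene models, small RNAs and chemoreceptor families were passed over. It further took up to 4 members with the lowest p of each list described, and always Pten, Hdc, Il6, Igf1, Ar, Nkx3-1, Mki67 and Adipoq.

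Alternatives were a replicate block, quantile normalization, centring of arrays on their median, no filter or a filter on 50% of genes, the mean of all probe sets of a gene, leaving out each mouse in turn, array weights, a trended and robust variance prior, an ordinary per-gene model without moderation and a fold minimum of 2. A skeletal muscle covariate, leaving out 3 muscle-rich libraries and testing all probe sets were added later. An alternative for linear values was not run, as the values were already on a log scale.

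The procedure was tested on simulated data for 16635 genes in 5 against 5 arrays. Of 50 genes changed at each size, 42% were recovered at 1.5-fold, 80% at 2-fold, 96% at 4-fold and 100% at 8-fold, with 5 false calls. With no change simulated it made 0 adjusted calls and 169 calls by the looser criterion. Simulated genes varied independently, unlike genes in tissue, so these shares do not cover correlated variation. All 200 changed genes were tested in 1 set, so those with large changes eased the adjusted threshold for the rest. With fewer true changes, smaller shares would be recovered on average. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.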

Results

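Gene expression was measured on whole-transcript oligonucleotide arrays in the prostates of 10 male C57BL/6 mice, 1 array per mouse. Every mouse carried a Cre recombinase driven by the probasin promoter, which is active in prostate epithelium, and floxed alleles of the tumour suppressor Pten, a combination that is used as a model of prostate cancer. A high-fat diet (HFD) was fed to 5 mice and a control diet (CD) to 5 mice from the age of 5 weeks, and tissue was taken at 22 weeks. The log2 values ran from 0.31 to 13.64, with array medians between 4.39 and 4.54. Pairs of arrays correlated across the 16635 tested genes with r between 0.901 and 0.982, a description across genes, which are not independent replicates. None of the 45 pairs of arrays held identical values. The number of arrays, 5 per diet, limits the precision of every value below.

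The single comparison asked how expression in the prostates of these cancer-prone mice differed between the high-fat and the control diet. Interferon-response genes, which cells switch on during antiviral defence, were higher as a group in HFD prostates, and all 23 measured members had a higher mean. Their list mean was 7.53 ± 0.45 (SD, n = 5) in HFD against 6.82 ± 0.35 in CD (camera, adjusted p = 8.73e-18; adjusted p = 0.308 with an estimated correlation between its genes). Marker lists of neutrophils, macrophages, B cells and collagen-producing fibroblasts were also higher, and the luminal epithelial list was lower, at 10.36 ± 0.16 against 10.61 ± 0.14 (each with an adjusted p = 0.308 with an estimated correlation). The correlation estimated within the interferon list was 0.614, far above the preset of 0.01 behind its first p-value. In other splits of the 10 mice, described below, camera at that preset called a median of 10 of the 30 lists. The camera p-values at the preset therefore overstate the evidence for the lists. Among single genes, Oas2, an antiviral sensor of double-stranded RNA, was 2.93-fold higher in HFD, and Gsdmc2, of the gasdermin family of membrane pore-forming proteins, was 3.02-fold lower. Both genes separated the diets in all mice, but no gene of the 16635 tested passed the threshold (limma, Benjamini-Hochberg adjusted p of 0.209 for both, the lowest of all genes). At an unadjusted p under 0.05 there were 1047 genes, 413 higher and 634 lower, where chance alone gives about 832 on average. In other splits of the 10 mice, described below, that count ran from 177 to 2509, so 1047 does not show an excess over chance. It was 803 without CD 1 and 1586 without HFD 5.

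Of the 23 interferon-response genes, 13 were higher at an unadjusted p under 0.05. When adjusted over the list alone 11 passed, while 0 passed when adjusted over all genes. Oas2 measured 8.0 ± 0.34 in HFD and 6.45 ± 0.43 in CD (SD, n = 5), and its relative Oas3 7.31 ± 0.61 and 6.12 ± 0.66. Usp18, which removes the ubiquitin-like protein Isg15 from its targets, measured 8.99 ± 0.54 and 7.86 ± 0.62, and the guanylate-binding protein gene Gbp3 5.69 ± 0.32 and 4.96 ± 0.37. Cxcl10, a chemokine that attracts T cells, had a log2 difference of 1.10 (SE 0.343). Outside the list, the interferon-inducible genes Ifi202b and Ifi204 had log2 differences of 0.97 (SE 0.235) and 0.96 (SE 0.270). Slfn4, a Schlafen family gene of myeloid cells, had the largest difference among the named genes with a higher mean in HFD, 4.08-fold. It measured 6.76 ± 1.09 against 4.73 ± 0.70, with 4 of 5 HFD mice above every CD mouse. Oas2, Oas3, Gbp3, Ifi202b, Ifi204 and Slfn4 belong to families with similar sequences, so the probe signal of each is uncertain between relatives. Without the 3 libraries rich in skeletal muscle transcripts that are described below, the list differed by 0.90 and 11 genes passed when adjusted over the list alone.

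**Figure D1:**
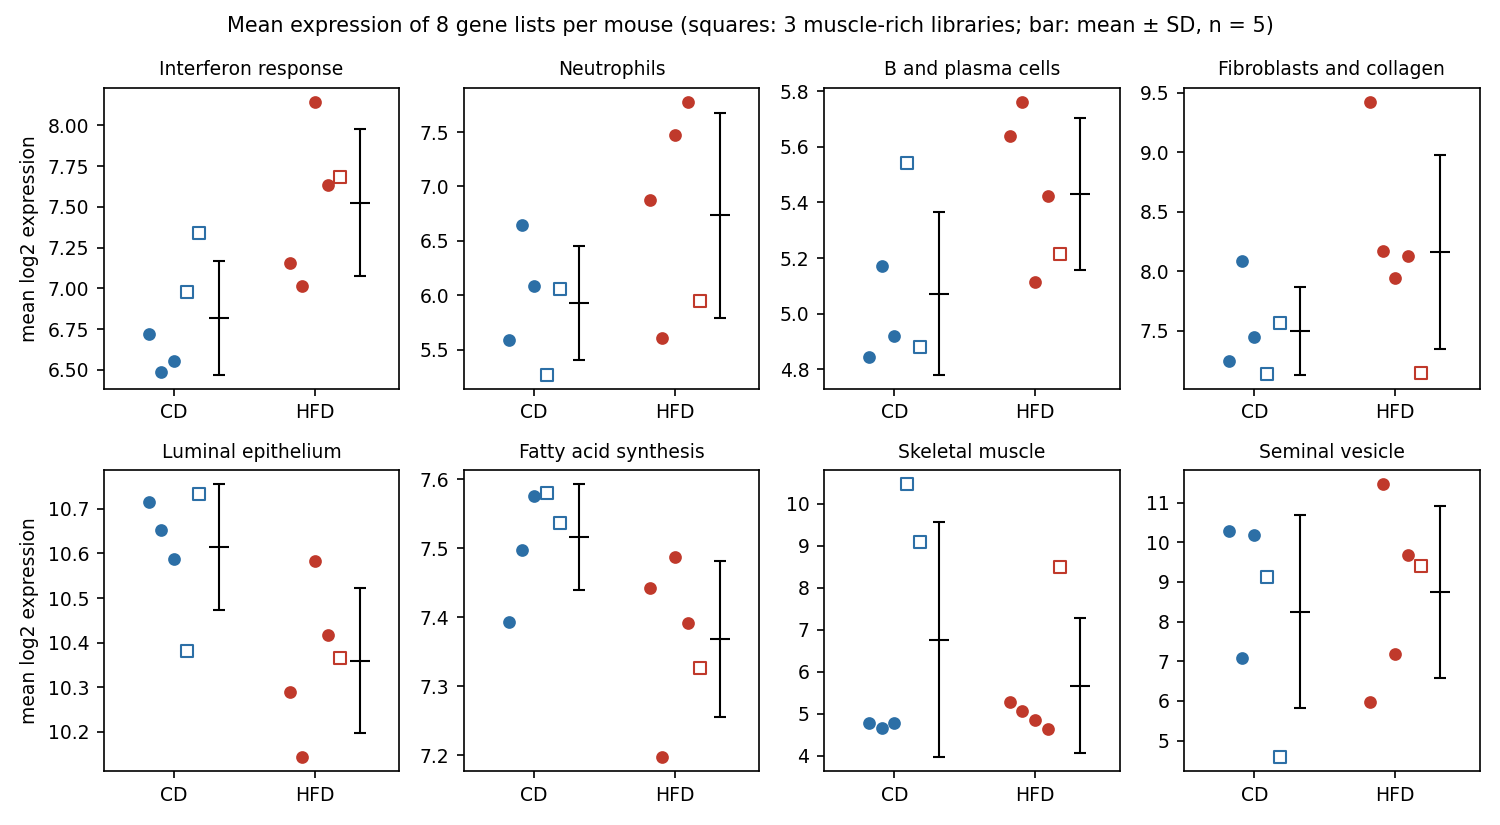
Mean log2 expression of 8 gene lists (vertical axes) in each mouse of the control diet (CD, blue) and the high-fat diet (HFD, red), with the group mean and SD beside the points (n = 5). Squares mark the 3 libraries rich in skeletal muscle transcripts, whose muscle list means were 8.50, 9.09 and 10.48, and in the interferon-response panel 3 of 5 HFD mice lie above every CD mouse.

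Marker lists of several immune cell types were higher in HFD. The list of neutrophils and granulocytic myeloid cells averaged 6.74 ± 0.94 against 5.93 ± 0.53 (camera, adjusted p = 1.29e-07; adjusted p = 0.308 with an estimated correlation). In 3 of 5 HFD mice the list mean lay above every CD mouse. The neutrophil difference of 0.81 ran from 0.55 without HFD 4 to 1.09 without HFD 2 when mice were left out in turn. Of this list's genes 20 of 22 were higher, 4 of them at an unadjusted p under 0.05. Those were Ly6g, with a log2 difference of 0.75 (SE 0.305), the calgranulin gene S100a9 with 1.62 (SE 0.663), the neutrophil elastase gene Elane with 0.32 (SE 0.135; 0.21 without the 3 muscle-rich libraries described below) and the lectin receptor gene Clec4e with 1.65 (SE 0.689). Macrophage and monocyte genes averaged 7.35 ± 0.44 against 6.92 ± 0.40 (adjusted p = 2.84e-08; adjusted p = 0.308 with an estimated correlation). Of these 22 of 23 were higher, among them the Fc receptor genes Fcgr4 with 0.79 (SE 0.249) and Fcgr1 with 0.71 (SE 0.244) and the chemokine receptor gene Ccr2 with 0.63 (SE 0.234). B cell and plasma cell genes averaged 5.43 ± 0.27 against 5.07 ± 0.29 (adjusted p = 7.03e-08; adjusted p = 0.308 with an estimated correlation), and 14 of 16 were higher. When adjusted over the list alone, 4 B cell genes passed. They were Ms4a1, which encodes a B cell surface protein, with a log2 difference of 1.07 (SE 0.341) whose size is uncertain because the CD mean of 3.50 lay under the filter limit of 3.78 for dim genes, Cd79b and Cd22, both of the B cell receptor complex or its regulators, with 0.57 (SE 0.166) and 0.33 (SE 0.10), and the B cell coactivator gene Pou2af1 with 0.45 (SE 0.107). That count became 0 without the 3 muscle-rich libraries, with 16 of 16 genes higher and a list difference of 0.51. T and NK cell genes averaged 5.20 ± 0.21 against 5.00 ± 0.13 (adjusted p = 5.85e-05; adjusted p = 0.308 with an estimated correlation), with Cd2 at a log2 difference of 0.31 (SE 0.0983). This list's difference of 0.21 became 0.12 without HFD 1. Genes of class II antigen presentation averaged 6.54 ± 0.26 against 6.28 ± 0.28 (adjusted p = 0.000168; adjusted p = 0.308 with an estimated correlation), 13 of 14 being higher. The class II difference of 0.25 became 0.17 without CD 4.

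Signalling lists tied to inflammation were also higher. NF-kB targets with cytokines and chemokines averaged 7.44 ± 0.55 in HFD and 6.98 ± 0.48 in CD (camera, adjusted p = 1.61e-05; adjusted p = 0.308 with an estimated correlation). Of these genes 25 of 28 were higher, 1 of them at an unadjusted p under 0.05. The chemokine genes Ccl7 with 0.47 (SE 0.186) and Ccl20 with 1.54 (SE 0.716) had the lowest p-values. The NF-kB list's difference of 0.46 ran from 0.31 without HFD 4 to 0.63 without CD 2 when mice were left out in turn. It was 0.32 with the skeletal muscle list mean as a covariate. The list of IL6, JAK and STAT3 signalling averaged 7.31 ± 0.32 and 7.03 ± 0.34 (adjusted p = 0.000359; adjusted p = 0.308 with an estimated correlation). Its lowest p-values belonged to the interleukin-10 receptor gene Il10ra at 0.60 (SE 0.192) and the transcription factor gene Cebpb at 0.55 (SE 0.196). This list's difference of 0.28 became 0.17 with the skeletal muscle list mean as a covariate. The transcript of the cytokine gene Il6 itself measured 3.28 ± 0.19 in HFD and 2.82 ± 0.28 in CD, under the filter limit of 3.78 for dim genes, so it was left out of the main test. With no filter its log2 difference of 0.47 (SE 0.148) did not pass (limma, unadjusted p = 0.00894, adjusted p = 0.828). Immediate early genes averaged 7.28 ± 0.29 and 7.02 ± 0.18 (adjusted p = 0.000278; adjusted p = 0.308 with an estimated correlation). Of these 15 of 19 were higher, including the matricellular protein gene Ccn1 with 1.15 (SE 0.345).

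The stromal and epithelial lists differed in both directions. All 21 measured genes of the fibroblast and collagen matrix list were higher in HFD, at a mean of 8.16 ± 0.82 against 7.50 ± 0.37 (camera, adjusted p = 7.98e-09; adjusted p = 0.308 with an estimated correlation). The collagen genes Col3a1 and Col1a1 had log2 differences of 1.03 (SE 0.458) and 1.07 (SE 0.526). This list's difference of 0.66 became 0.35 without HFD 1, with Col3a1 and Col1a1 at 0.66 each. Plod2, an enzyme that modifies collagen lysines, was 2.21-fold higher. Basal epithelial genes averaged 7.50 ± 0.30 against 7.09 ± 0.33 (adjusted p = 0.000439; adjusted p = 0.308 with an estimated correlation). Higher means were found for 13 of 14, with the keratin genes Krt6a at 1.51 (SE 0.483) and Krt17 at 0.61 (SE 0.210) and the desmosomal cadherin gene Dsg3 at 1.44 (SE 0.574). In the luminal and progenitor epithelial list 15 of 15 genes were lower in HFD (adjusted p = 0.00143; adjusted p = 0.308 with an estimated correlation). The prostate stem cell antigen gene Psca differed by -1.43 (SE 0.492) and Cd24a by -0.31 (SE 0.108). Urothelial genes averaged 6.53 ± 0.36 against 6.93 ± 0.25 (adjusted p = 0.0082; adjusted p = 0.308 with an estimated correlation). Of these 8 of 10 were lower, and the uroplakin gene Upk1b, with -1.18 (SE 0.230), passed when adjusted over the list alone. The urothelial call was lost without HFD 5 (adjusted p = 0.074), without CD 4 (adjusted p = 0.0658) and without the 3 muscle-rich libraries (adjusted p = 0.168), while the difference of -0.40 stayed at -0.37, -0.34 and -0.32. Upk1b did not pass over the list alone in that last setting. Cell cycle genes averaged 6.02 ± 0.21 against 5.79 ± 0.25 (adjusted p = 1.15e-06; adjusted p = 0.308 with an estimated correlation). Higher means were found for 26 of 28, with the cyclin gene Ccna2 at 0.47 (SE 0.184), Cdk1 at 0.49 (SE 0.209) and the proliferation marker Mki67 at 0.51 (SE 0.284). The cell cycle difference of 0.23 became 0.14 without CD 1, with Cdk1 at 0.30 and Mki67 at 0.29.

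The 15 named genes with a lower mean in HFD, from -2.29 to -1.17 on the log2 scale, did not pass the threshold. Olfm4, a secreted glycoprotein of epithelial progenitors, had the largest difference among them, at 5.43 ± 0.89 in HFD against 7.72 ± 0.96 in CD (SD, n = 5), 4.90-fold lower. Hepacam2 was 3.67-fold lower, at 5.08 ± 0.25 against 6.96 ± 0.77, and B4galnt2, a glycosyltransferase that caps mucin-type glycans, 3.31-fold lower, at 9.02 ± 0.86 against 10.75 ± 0.46. Gsdmc2 measured 8.35 ± 0.40 against 9.95 ± 0.37 and its close relative Gsdmc3 9.45 ± 0.45 against 10.81 ± 0.25. Their probe signals are uncertain between relatives, as is that of the kallikrein family gene Klk1b11 with a log2 difference of -1.19 (SE 0.331). Fa2h, which adds a hydroxyl group to fatty acids of sphingolipids, differed by -1.40 (SE 0.280), and Hsd11b2, which inactivates glucocorticoids, by -1.36 (SE 0.367). Abcg8, a part of a sterol exporter, differed by -1.22 (SE 0.254), the endoplasmic reticulum stress sensor gene Ern2 by -1.22 (SE 0.264) and the mucin-glycosylating enzyme gene Galnt5 by -1.19 (SE 0.282). The annexin gene Anxa13 differed by -1.37 (SE 0.362) and the keratin gene Krt78 by -1.22 (SE 0.290). Atoh1, a transcription factor of secretory cell fate, differed by -1.17 (SE 0.306), with CD 3 at 7.24 and the other CD mice between 5.47 and 5.97, and by -0.85 without CD 3. The diets did not overlap for 203 of all tested genes in one or the other direction, 1.22% where chance gives 0.794% on average. The spread of that chance share among correlated genes was not measured, so no excess over chance is read from it.

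**Figure D2:**
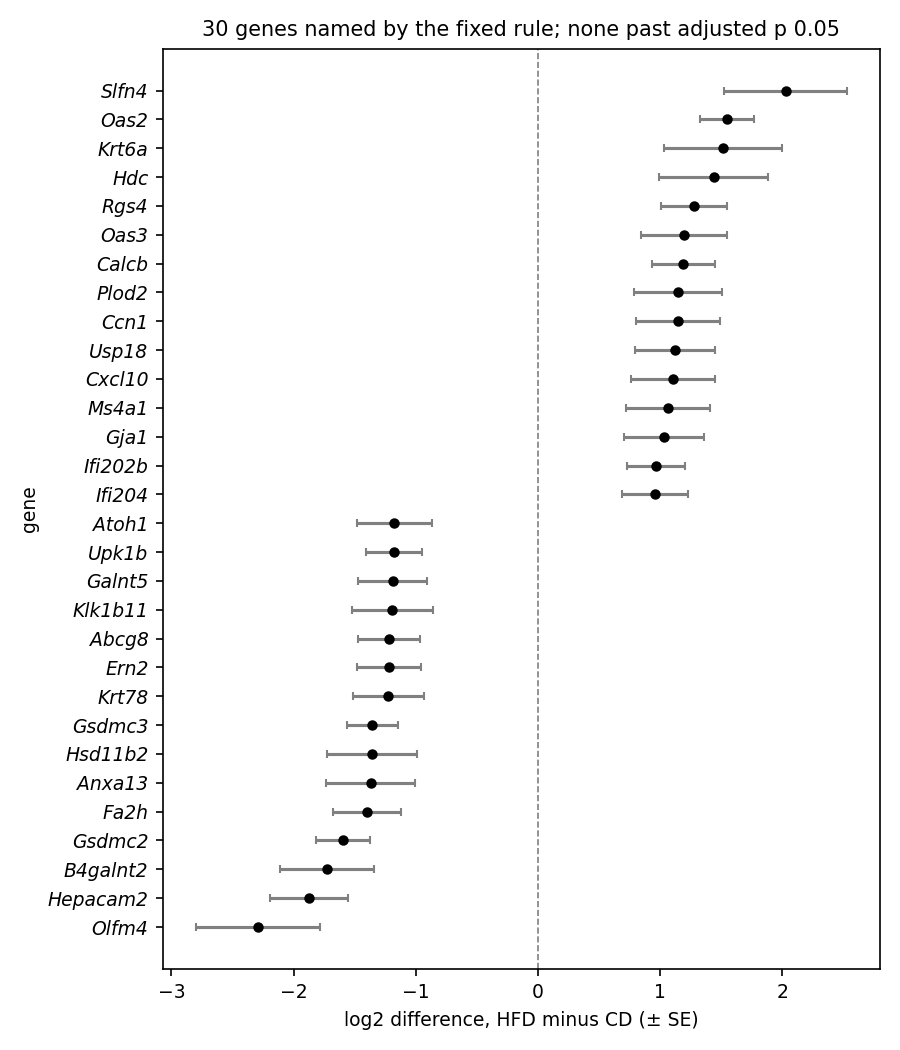
Log2 difference between HFD and CD prostates (horizontal axis, error bars SE, 5 mice per diet) for the 15 named genes with a higher mean in HFD and the 15 with a lower mean (vertical axis). The differences run from -2.29 for Olfm4 to 2.03 for Slfn4, and no adjusted p among them was under 0.209.

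Histidine decarboxylase, Hdc, the enzyme that makes histamine, measured 6.94 ± 0.98 in HFD and 5.50 ± 0.60 in CD, a 2.71-fold difference. In 4 of 5 HFD mice it lay above every CD mouse, but it did not pass the threshold (limma, unadjusted p = 0.00838, adjusted p = 0.682). The list of histamine synthesis, receptors and breakdown averaged 5.60 ± 0.08 against 5.38 ± 0.20 (camera, adjusted p = 0.233), with 5 of 9 genes higher. Mast cell markers averaged 5.34 ± 0.24 and 5.38 ± 0.22 (adjusted p = 0.985), 4 of 10 being higher, and 9 further mast cell genes lay below the filter for dim genes. Hdc is itself a member of the histamine and mast cell lists and raises both means. Their median log2 differences were 0.04 and -0.02. The remaining named genes with a higher mean in HFD were Rgs4, a regulator of G protein signalling, with a log2 difference of 1.28 (SE 0.270), the calcitonin gene-related peptide gene Calcb with 1.19 (SE 0.258) and the gap junction gene Gja1 with 1.03 (SE 0.330).

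**Figure D3:**
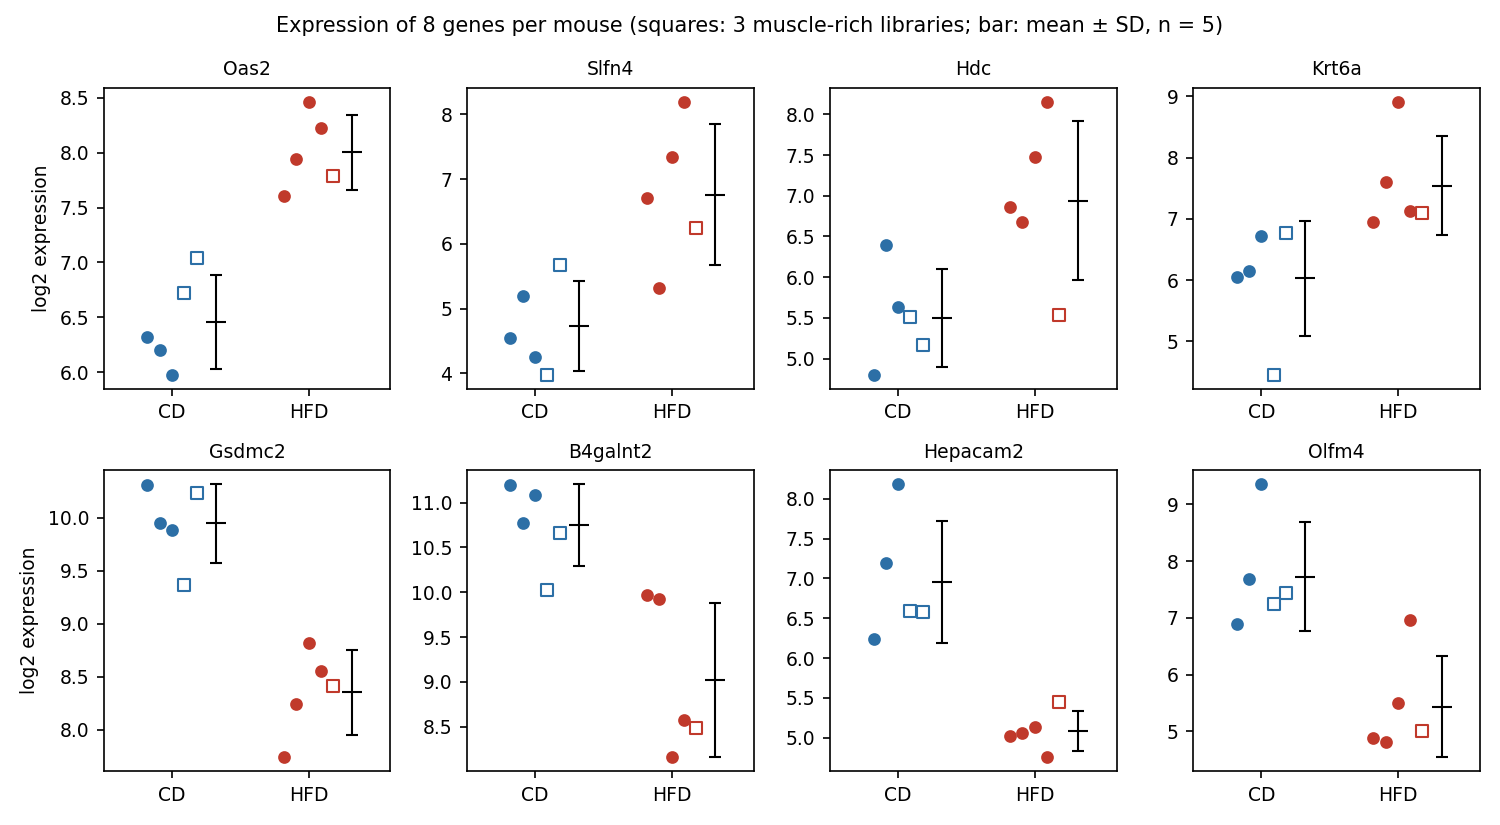
Log2 expression (vertical axes) of 8 named genes in each mouse of the control diet (CD, blue) and the high-fat diet (HFD, red), with the group mean and SD beside the points (n = 5) and squares for the 3 libraries rich in skeletal muscle transcripts. Oas2, Krt6a, Gsdmc2, B4galnt2 and Hepacam2 do not overlap between the diets, whereas for Hdc, Slfn4 and Olfm4 4 of 5 HFD mice lie beyond every CD mouse.

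Lists of lipid metabolism had small differences. Fatty acid synthesis genes averaged 7.37 ± 0.11 in HFD and 7.52 ± 0.08 in CD, 14 of 21 being lower, without passing the threshold (camera, adjusted p = 0.0574). The list passed without HFD 1, HFD 4 or CD 1 (adjusted p of 0.039, 0.0407 and 0.017; differences of -0.17, -0.15 and -0.18 against -0.15) and with no filter on dim genes (adjusted p = 0.0369, with the same difference). Its camera adjusted p rose to 0.229 without HFD 2, 0.198 without CD 3 and 0.182 with array weights, at differences of -0.10, -0.13 and -0.15. Without the 3 muscle-rich libraries the difference was -0.11 (camera, adjusted p = 0.177; exact permutation p = 0.314). Its lowest members by p were the elongase gene Elovl5 with a log2 difference of -0.34 (SE 0.0926), the lipogenic transcription factor gene Srebf1 with -0.44 (SE 0.136) and the malic enzyme gene Me1 with -0.54 (SE 0.214). Fatty acid oxidation genes and PPAR targets averaged 6.97 ± 0.16 and 7.08 ± 0.15, 21 of 24 being lower (adjusted p = 0.0479; adjusted p = 0.315 with an estimated correlation). The PPAR target Angptl4, an inhibitor of lipoprotein lipase, had a higher mean in HFD with 0.81 (SE 0.260), and 0.50 without the muscle-rich libraries. The oxidation call was lost without HFD 2 (adjusted p = 0.291), HFD 4 (0.0824), CD 3 (0.0798) or CD 4 (0.341), the library with the highest skeletal muscle list mean. The difference of -0.11 became -0.06, -0.08, -0.12 and -0.04 in these settings. It was -0.10 without the 3 muscle-rich libraries, where the call was also lost (adjusted p = 0.149), and -0.06 with the skeletal muscle list mean as a covariate (adjusted p = 0.189). The call ended as well with quantile normalization (adjusted p = 0.0751), with the filter on 50% of genes (0.119) and with array weights (0.182), at differences of -0.10, -0.10 and -0.11. Cholesterol synthesis genes averaged 7.31 ± 0.23 and 7.31 ± 0.11 (adjusted p = 0.642), with a mean difference just above 0 and a median of -0.02. Adipocyte markers averaged 5.80 ± 0.32 and 5.74 ± 0.39 (adjusted p = 0.361), and without the muscle-rich libraries the difference rose from 0.06 to 0.33 and that list passed (adjusted p = 0.0177; exact permutation p = 0.229). Adipoq, the adipocyte hormone gene, differed by 0.46 (SE 0.258, adjusted p = 0.799), but by 0.91 without the muscle-rich libraries and 0.30 without CD 3. Insulin and IGF signalling genes averaged 7.56 ± 0.13 and 7.49 ± 0.08 (adjusted p = 0.136), and Igf1 differed by 0.48 (SE 0.268, adjusted p = 0.799), but by 0.26 without HFD 1 and 0.75 without the muscle-rich libraries. The list's difference of 0.07 became 0.02 without HFD 1, 0.04 without CD 3 and 0.11 without the muscle-rich libraries.

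Androgen-response genes averaged 7.40 ± 0.12 in HFD and 7.45 ± 0.18 in CD (camera, adjusted p = 0.506), with Homer2 at -0.65 (SE 0.208) and the serine protease gene Tmprss2 at -0.44 (SE 0.165). Prostate secretory protein genes averaged 7.04 ± 0.83 and 7.13 ± 0.65 (adjusted p = 0.996), and neuroendocrine markers 5.17 ± 0.28 and 5.12 ± 0.17 (adjusted p = 0.641). For the mast cell and prostate secretory lists the mean and median were lower in HFD while camera's direction was higher, and for the neuroendocrine list the mean was higher and the median lower. Genes of the NRF2 and oxidative stress list averaged 7.96 ± 0.12 and 8.05 ± 0.11 (adjusted p = 0.147), passing only without HFD 1 among the mice left out in turn (-0.13 against -0.09, adjusted p = 0.0445). Hypoxia and glycolysis genes averaged 8.63 ± 0.30 and 8.49 ± 0.19 (adjusted p = 0.0213; adjusted p = 0.595 with an estimated correlation). That call was lost without HFD 1, HFD 3, HFD 4, HFD 5 or CD 4 (adjusted p between 0.0537 and 0.183), the difference of 0.14 becoming 0.11, 0.09, 0.09, 0.15 and 0.07. It was also lost without the 3 muscle-rich libraries, at 0.07 (adjusted p = 0.228), whereas without HFD 2 the difference rose to 0.27 (adjusted p = 7.8e-06). Endothelial markers averaged 6.37 ± 0.41 and 6.25 ± 0.24 (adjusted p = 0.12) and passed without HFD 2, HFD 5, CD 2 or CD 4 (adjusted p between 0.00399 and 0.0338), the difference of 0.11 rising to 0.19, 0.22, 0.18 and 0.17. They also passed with array weights (adjusted p = 0.00314) and without the muscle-rich libraries (0.22, adjusted p = 0.00832). The endothelial difference turned to -0.04 without HFD 1, and fell to 0.06 without CD 1 and 0.05 without CD 5. Pten, Ar and Nkx3-1 had no singly named probe set in the annotation used and were not analysed here. Nor was the red blood cell list, of which 3 of 12 genes were measured.

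Transcripts of neighbouring tissues varied strongly between mice. The skeletal muscle list averaged 8.50 in HFD 5, 10.48 in CD 4 and 9.09 in CD 5, and between 4.63 and 5.28 in the other mice. Its group means were 5.66 ± 1.61 in HFD and 6.76 ± 2.81 in CD, with 15 of 15 genes lower in HFD (camera, adjusted p = 0.0181; adjusted p = 0.691 with an estimated correlation). The difference of -1.10 fell to -0.17 without CD 4 and to -0.51 without CD 5 (adjusted p of 0.856 and 0.273), and turned to 0.21 without all 3 muscle-rich libraries. The call was also lost without HFD 2, HFD 3 or HFD 4, at -0.94, -0.89 and -0.84 (adjusted p between 0.0666 and 0.104), and with the filter on 50% of genes (-1.05, adjusted p = 0.0782). Without HFD 5 the difference was -1.81. Smooth muscle genes averaged 7.20 ± 0.61 and 6.93 ± 1.00 (adjusted p = 0.0476; adjusted p = 0.691 with an estimated correlation), with CD 4 at 8.69. That call was lost without HFD 2, HFD 3, HFD 5, CD 1, CD 2, CD 3 or CD 5 (adjusted p between 0.0689 and 0.563), the difference of 0.28 falling to 0.07 without HFD 2 and staying at 0.25 without HFD 3. The difference was smaller as well without CD 1, CD 2, CD 3 or CD 5. The call also ended with the replicate number as a block, with quantile normalization and with the mean of probe sets per gene (adjusted p of 0.0762, 0.0641 and 0.0576), at differences of 0.28, 0.29 and 0.26. The difference rose to 0.72 without CD 4 (adjusted p = 5.74e-10) and to 0.81 without the 3 muscle-rich libraries (adjusted p = 2.24e-09). Seminal vesicle genes averaged 8.74 ± 2.17 and 8.25 ± 2.43 (adjusted p = 0.361), ranging from 4.57 in CD 5 to 11.47 in HFD 2, and passed without HFD 1 (adjusted p = 0.0205), the difference of 0.49 becoming 1.19. It turned to -0.19 without HFD 2, -0.43 without CD 5 and -0.61 without the muscle-rich libraries.

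Over the 30 lists, camera with its preset correlation called 18, of which 14 were higher and 4 lower in HFD, and with an estimated correlation it called 0. With the mouse as the unit, a 2-sided exact permutation test of the list means gave an unadjusted p = 0.0317 for the interferon-response, luminal epithelial and fatty acid synthesis lists. No list passed this test after adjustment (lowest adjusted p = 0.317). Over 30 lists the smallest possible p of 0.00794 cannot pass in 1 list alone, so this test had little power to call single lists. The number of lists at an unadjusted p under 0.05 in this test ranged from 0 to 4 across the alternatives. It was 0 without CD 2 and without CD 3, and 1 with arrays centred on their median, where luminal epithelium had an exact permutation p = 0.0635 and fatty acid synthesis p = 0.103. With the replicate number as a block it was 0 by construction. There the exact permutation p cannot fall under 0.0625, the value of the interferon-response list. By the looser criterion of at least 1.5-fold with an unadjusted p under 0.05, 236 genes differed, 126 higher and 110 lower. That count was 447 without HFD 5 and 426 without the 3 muscle-rich libraries.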

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

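The sorting of splits by muscle-rich libraries, and the widening of the first test below from 34 to 104 genes, were chosen after the results were seen, and the other tests in this part were not. Within each diet, the gap between an extreme mouse and its nearest neighbour was compared with the range of the group for 104 genes and 30 lists. Of 268 such tests 12 stood out, where about 13.4 are expected by chance, 8 of them in CD. The skeletal muscle list mean of HFD 5 was 8.50, with the other HFD mice between 4.63 and 5.28. The smooth muscle list mean of CD 4 was 8.69, against 6.29 to 6.74 in the other CD mice. CD 4 also stood apart in fatty acid oxidation and PPAR targets, at 7.35 against 6.99 to 7.04. CD 3 was low in the insulin and IGF signalling list, at 7.35 against 7.50 to 7.55. CD 3 was high in Atoh1, at 7.24 against 5.47 to 5.97, and low in Sfn, at 7.28 against 7.48 to 7.56. CD 4 was low in Krt19, at 11.01 against 11.61 to 11.67, and in Tmprss2, at 11.04 against 11.76 to 11.88. It was high in Fads2, at 9.58 against 7.63 to 8.08. HFD 2 was low in Herc3, at 5.38 against 6.14 to 6.25. HFD 3 was high in Nr1d2, at 6.76 against 6.26 to 6.30, and HFD 5 low in Asah1, at 7.99 against 8.42 to 8.58.

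Of the 126 ways to split the 10 mice into 5 and 5, 100 were drawn, the real one included. For genes past the adjusted threshold, 100 of 100 splits gave at least the real count of 0, and the highest other count was 110. For the looser criterion, 20 of 100 splits gave as many as the real 236 genes, and the highest other count was 908, so chance cannot be excluded as the origin of that count. The splits with 110 and with 908 genes both placed the 3 muscle-rich libraries on one side. The 17 splits of that kind had a median of 257 genes by the looser criterion, against 71 in the other splits. Counts in that kind went as low as 79, and a split that divided these libraries reached 711. As the sorting was chosen after the counts were seen, muscle content cannot be told apart from other structure of the samples. For gene lists, 1 of 100 splits, the real one, reached 18 called lists, and the highest other count was 17. This met the bound of fewer than 5 in 100, by a narrow margin and only for camera at its preset correlation. The real count was 16 with quantile normalization, 15 without CD 4 and 0 with an estimated correlation. Chance is therefore not excluded as the origin of this count. The other splits called a median of 10 lists.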

How the results depend on the processing

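The muscle covariate, the fits without the 3 muscle-rich libraries and the fit of all probe sets were chosen after seeing the data. No named gene passed in limma under any alternative, and an ordinary per-gene model also gave 0 genes (1049 at an unadjusted p under 0.05). All 91 named genes kept their direction in the alternatives that included them. Most had been chosen for a large fold or a low p in these same data, so this outcome was likely beforehand and is no independent support. Tested over all 26008 probe sets above the filter, named or not, 1 probe set passed. The count of 236 genes by the looser criterion became 405 with array weights, 62 at a fold minimum of 2, 426 without the muscle-rich libraries, and 187 to 447 when mice were left out in turn, the highest without HFD 5. The cause was not tested, except that a higher fold minimum takes fewer genes by construction. The 18 called lists became 0 with an estimated correlation and 0 with fry, both of which use the correlation among a list's genes, and 15 to 20 when mice were left out in turn.

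Deviations of mice that share a number correlated between -0.495 and 0.254 and 0 of 5 HFD mice correlated best with their own number, so the numbers were not taken as pairs. With the replicate number as a block there were 0 adjusted genes, 205 genes by the looser criterion and 17 lists.

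The mean difference turned in 9 of 30 lists, for causes not tested, and 1 of those had been called. Without the muscle-rich libraries it was 0.21 for skeletal muscle (adjusted p = 0.0242), 0.0596 for mast cells, -0.0693 for cholesterol synthesis and -0.61 for the seminal vesicle. With the filter on 50% of genes it was 0.14 for mast cells, -0.0697 for adipocytes and 0.22 for prostate secretory proteins, and with the muscle covariate 0.16 for the last. When mice were left out in turn, the ranges were -0.10 to 0.0245 for mast cells, -0.074 to 0.077 for cholesterol synthesis, -0.0642 to 0.18 for adipocytes, -0.12 to 0.0027 for androgen response, -0.39 to 0.14 for prostate secretory proteins, -0.0556 to 0.11 for neuroendocrine cells, -0.43 to 1.19 for the seminal vesicle and -0.0443 to 0.22 for endothelium. Probe sets near background have compressed differences, which limits statements on dim genes such as Il6.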

Other observations

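The clock, sphingolipid and gut gene lists and every test in this part were chosen after the main results were seen, and each prediction was written before the tested value was seen. For the interferon list a stricter requirement was added after the values of its covariate tests were seen, as stated there.

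Several circadian clock genes had different means in the diets, and none passed the threshold over all genes. Nr1d1 and Nr1d2, repressors in the clock's feedback loop, had log2 differences of -1.16 (SE 0.297) and -0.59 (SE 0.144) in HFD and drew attention first. Dbp, with -0.70 (SE 0.246), and Tef, with -0.56 (SE 0.159), are clock output factors that peak close to Nr1d1, and all 9 measured genes of that phase had a lower mean in HFD. Of the genes that peak at the opposite phase, 5 of 5 had a higher mean, including Cry1 with 0.34 (SE 0.111), Arntl with 0.36 (SE 0.151) and Npas2 with 0.50 (SE 0.226). Among the same genes, Per1 (-0.04), Ciart (-0.01), Bhlhe41 (-0.08) and Clock (0.02) barely moved. Over members not looked at before, the mean of the first phase differed by -0.27 (exact permutation p = 0.0317, adjusted p = 0.0794) and that of the opposite phase by 0.32 (exact permutation p = 0.00794, adjusted p = 0.0397). Both were adjusted over only the 5 lists of this part, not over the 30 lists above, so they cannot be set beside the adjusted values there. Nr1d1 and Nr1d2 had prompted the clock lists in these same mice, a selection that the p-values leave out. The names here were chosen after their values were seen.

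Of 35 measured genes of sphingolipid synthesis and breakdown, 13 were lower in HFD at an unadjusted p under 0.05 and 1 was higher, the ceramide synthase gene Cers6 with 0.56 (SE 0.163). Its relative Cers3 differed by -0.997 (SE 0.180), the acid ceramidase gene Asah1 by -0.65 (SE 0.126) and the serine palmitoyltransferase gene Sptlc3 by -0.87 (SE 0.235), beside Fa2h. It was hypothesised that the pathway was lower as a group. Over the 28 members not looked at before, the mean differed by -0.0294 (exact permutation p = 0.563), so the wider pathway could not be shown to differ, and the difference of -0.20 over all 35 members rests mainly on the genes that prompted the list. Of these 28 members 17 were lower and 11 higher, 6 and 1 of them at an unadjusted p under 0.05.

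Among 8456 probe sets above the filter that carry no symbol or several, 1 passed the threshold within that set. Probe set 17317472, whose annotation gives 2 symbols so that no gene is named, measured 8.09 ± 0.24 in HFD and 9.93 ± 0.40 in CD (SD, n = 5), a log2 difference of -1.83 (SE 0.198). Its limma adjusted p was 0.0131 among the unnamed probe sets and 0.0381 among all 26008 probe sets above the filter. All 5 HFD mice lay below every CD mouse.

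The higher interferon-response list in HFD was weighed against tissue composition. With the skeletal muscle list mean as a covariate the difference was 0.803 (SE 0.249) against 0.711 without it, and it was 0.90 without the 3 muscle-rich libraries, which argues against muscle content as the whole cause. With the macrophage and monocyte list mean as a covariate it was 0.654 (SE 0.313), and both covariate values met the bounds written beforehand for excluding a tissue, above 0.8 of the difference without the covariate and over 2 SE, but passed the first by less than their own SE. Under the requirement added after the values were seen, that the value less 1 SE exceed 0.5 of that difference, muscle stayed excluded and macrophages did not, so a share carried by more macrophages cannot be told apart from induction within the tissue. An effect of the diet itself stays open as a hypothesis, since diet was the only group factor and an infection or other shared exposure of a cage is not recorded in the labels, and new mice in several cages per diet, with interferon genes measured in sorted macrophages and epithelium, would test it.

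The 15 named genes with a lower mean in HFD, none of which passed, were weighed against admixed gut, because some of them, such as Hepacam2, Ern2 and Atoh1, are known from secretory cells of the intestine. Gut absorptive and colon markers averaged 5.56 ± 0.52 in HFD and 5.41 ± 0.44 in CD (SD, n = 5), a difference of 0.153 (SE over 20 genes 0.116). That SE measures the spread over genes, and with the mouse as the unit no difference was detected (exact permutation p = 0.587). Intestinal tissue in the CD libraries would give a lower value in HFD. This was not seen, but with the spread between mice admixed gut was neither shown nor excluded. The abundant gut genes Lgals4 and Vil1 differed by 0.33 (SE 0.840) and -0.06 (SE 0.619) from CD levels of 8.83 and 7.81. Fabp2 was lower, at -1.01 (SE 0.369, limma unadjusted p = 0.0202), and Gpa33 differed by -0.29 (SE 0.518), while Car1 was higher, at 1.69 (SE 0.723, limma unadjusted p = 0.0394). Of 22 listed markers 20 were tested, and the filter for dim genes lets no gene below its limit be tested. Some lay near that limit of 3.78, such as Guca2b at 3.82 in HFD and 3.79 in CD. Of the 20 markers 1, Krt20, is also in the urothelial list. With the muscle covariate the median difference of the 15 genes was -1.37, against -1.36 without it, which argues against muscle content. Over a list of the gut secretory programme the difference was -0.32 (exact permutation p = 0.0873) and over its 22 members not looked at before -0.140 (p = 0.421), so whether a wider secretory programme was lower cannot be told apart from a change in these genes alone, and an effect of the diet on these genes stays an open hypothesis that measuring them in sorted epithelium of new mice would test.

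The lower Nr1d1 and Nr1d2 were weighed against the time of tissue collection. Over clock genes not looked at before, the mean of those in phase with Nr1d1 minus those against it was -0.588 in HFD relative to CD (exact permutation p = 0.00794, the smallest that permutations can give), with 5 of 5 HFD mice below every CD mouse and a range of -0.67 to -0.48 when mice were left out in turn. The direction is the one that a difference in clock phase between the groups would give. The test was prompted by Nr1d1 and Nr1d2 in these same mice, and genes of 1 feedback loop can vary together. The permutation p leaves that selection out, so it is no independent support. With the muscle covariate the mean difference of Nr1d1 and Nr1d2 was -0.862, against -0.875 without it, which argues against muscle content. With 1 array per mouse, a shift in phase cannot be told apart from a change in the levels of these genes. If the phase did differ, whether the time of collection or the diet was the cause stays open, as the labels give no collection time.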
